A study of Rattus norvegicus with 6 samples.

How the data were processed

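RNA was measured in 6 libraries of spinal cord tissue from rats with a contusion injury at the T9 segment, 3 from the Gel+US group and 3 from the Piezo Gel+US group. The labels give Rattus norvegicus, the Norway rat, as the organism. Per the labels' protocols, a tissue piece of about 5 mm3 was taken at the lesion centre, RNA was extracted with TRIzol, polyadenylated RNA was selected with oligo(dT) beads, and strand information was kept by dUTP in the second cDNA strand. Each library was assigned to its group by its treatment label, and each column of the deposited table to its library by the library name in the labels.

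The authors deposited a table of raw counts per gene, whole numbers that were not normalised, with gene names, positions and product descriptions. Fastp 0.19.7, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 are named in the submitters' processing notes, without their roles or settings, and whether counting used the strand is not given in the sources used here. The genome build is likewise not given. The table lists 33455 genes, of which 23240 had a count in at least 1 library. None of its gene identifiers occurred in the Norway rat RefSeq gene table of the GRCr8 assembly (0 matches), while 15093 genes shared a symbol with it. The table holds 18 sequences of autosome size against 20 Norway rat autosomes, and 2 of them each carried more than 100 genes of 2 Norway rat autosomes. The sequence name given for the mitochondrial genes is, from general knowledge, that of the black rat, Rattus rattus, and the 13 mitochondrial protein genes had 0 to 7 counts in total per library, while the 2 mitochondrial ribosomal RNAs took 0.129% to 0.332% of counts. The cause of the near absence of the protein genes was not tested. Reads of nuclear genes that differ between the species or that are missing from the reference used would be lost or shared between copies, which would lower such genes in both groups. Positions are therefore printed only as the deposited table gives them.

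Genes were compared with edgeR 4.0.16 in R 4.3.3, using trimmed mean of M-values (TMM) factors, the default low-count filter (filterByExpr, minimum count 10 and minimum total count 15) and the robust quasi-likelihood F test with group as the only term. P-values were adjusted by the Benjamini-Hochberg method over the 17066 genes tested, and a gene was called at an adjusted p below 0.05. Levels are CPM, counts scaled to a common library total, computed on the TMM-scaled library size and given as mean ± SD of 3 libraries, and 95% intervals of fold changes come from the same fit. A positive log2 fold change means higher in Piezo Gel+US. Library totals of 17212653 to 21436820 counts set the counting error, which was small beside the spread between animals. The common biological coefficient of variation was 0.382.

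Before the data were examined, 55 gene lists were fixed for cell types, neuronal functions, channels, matrix, pathways and technical features, along with the tests, most alternatives and the rule for named genes. Of 1300 list entries, 1124 were matched by symbol, 62 by a unique gene whose protein match carried the symbol, and 114 were not matched. The 53 lists with at least 5 genes tested were compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists. The test was repeated with a correlation estimated from the data and with fry, which asks whether members move on balance in 1 direction without comparing them with other genes. A list score is the mean over members of log2 CPM (prior count 2) after subtracting each gene's mean of the 6 libraries. Comparisons of 3 against 3 scores used an exact two-sided permutation test, whose smallest possible p is 0.1.

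Named genes are, for each direction, up to 10 called genes of largest fold change with log2 CPM of at least 0, a proper symbol and no overlap between groups, filled up to 5 with the genes of lowest p where fewer were called. To these were added members of lowest p from each called list and 17 genes fixed in advance. Gfap had no match and was not analysed here, and Il6 fell below the count filter.

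Replicate numbers occur in both groups. Deviations from the group means over all tested genes correlated between same-numbered libraries at 0.253 for replicate 1, 0.296 for replicate 2 and 0.251 for replicate 3. Every same-number correlation was above 0.1, which by the rule set for this check marks the numbers as pairing the samples. The main tests still used group alone, and the pairing entered only the block fit and the comparisons of equal numbers. The pairing is a reading of the data alone, since the labels do not say that a number marks a shared litter, surgery or day. One correlation between different numbers, Gel+US replicate 1 with Piezo Gel+US replicate 3, reached 0.198. With so few libraries there are few ways to match numbers, so the correlations cannot settle whether a number marks a real pair. A fit with the replicate number as a block was run as an alternative. Other alternatives were DESeq2 1.42.0, limma-voom with sample quality weights, other scaling factors, other count filters, protein-coding genes only, other thresholds and leaving out each library in turn. Libraries of a group were compared in pairs and none agreed within counting noise (chi-square per degree of freedom at least 54.5).

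The gene test was tested on simulated counts with the means, library sizes and dispersions of this comparison, in which 50 genes were changed at each of 4 sizes among 16779 genes. It recovered 2 of the 50 genes changed 2-fold, 32 changed 4-fold, 44 changed 8-fold and 43 changed 16-fold, with 12 false calls. At a reduced dispersion (the estimate divided by 16), 45 of 50 genes changed 2-fold and all 50 at each larger size were recovered, with 25 false calls among 16916 genes. In both runs all changed genes were seeded together and genes were drawn independently, whereas genes of the data varied together. The recovered numbers therefore do not give the recovery of a few changed genes in the data. In a simulation with independent genes, the list test called 10 of 10 shifted lists and 0 of 40 unshifted ones. In the data the estimated correlation between members was 0.327 for the Schwann cell, 0.838 for the neuron and 0.880 for the ribosomal protein list. It was 0.0156 for the axon guidance list. The simulation therefore does not give the rate of false list calls in these data.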

Results

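Gene expression was measured in the lesion centre of the rat spinal cord after contusion at the T9 segment, in animals that received ultrasound with a gel (Gel+US, n = 3) or with a piezoelectric gel (Piezo Gel+US, n = 3). A piezoelectric material turns mechanical strain, here from the ultrasound, into electrical charge. Ultrasound at 100 Hz and 1 W/cm2 was applied for 10 min a day over 4 weeks. The comparison addresses which transcripts differed in the injured tissue when the gel was piezoelectric. Total counts were 19492818, 17212653 and 20198203 in Gel+US replicates 1 to 3 and 18672101, 21436820 and 19132453 in Piezo Gel+US replicates 1 to 3.

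The genes of lowest p that met the naming rule on level, symbol and overlap included 2 semaphorins and 2 transporters, and none passed the test over all genes. Sema3d and Sema3c are secreted semaphorins that steer growing axons. They were lower in all 3 Piezo Gel+US libraries than in any Gel+US library, a separation that the naming rule required. Sema3d measured 27.6 ± 6.84 CPM in Gel+US and 12.9 ± 2.53 in Piezo Gel+US (log2 fold change -1.10, 95% interval -1.70 to -0.49), and Sema3c measured 64.0 ± 29.5 CPM in Gel+US and 25.3 ± 2.26 in Piezo Gel+US (log2 fold change -1.34, 95% interval -2.16 to -0.53). These lie on the same sequence, Sema3d at 143079794 to 143271014 and Sema3c at 147234052 to 147394229 on the plus strand in the coordinates of the deposited table, whose build is not named. Slc7a11, the cystine/glutamate antiporter, measured 21.3 ± 3.18 CPM in Gel+US and 10.7 ± 3.06 in Piezo Gel+US (log2 fold change -0.99, 95% interval -1.61 to -0.36). Slc2a12, a sugar transporter, and Crispld1 had log2 fold changes of -1.04 and -1.51. On the higher side, Ado, a cysteamine dioxygenase, measured 19.5 ± 0.393 CPM in Gel+US and 36.1 ± 9.94 in Piezo Gel+US (log2 fold change 0.89, 95% interval 0.33 to 1.45), and Lurap1 measured 10.7 ± 1.84 CPM in Gel+US and 19.5 ± 3.55 in Piezo Gel+US (log2 fold change 0.86, 95% interval 0.31 to 1.41). Gnb3, a G protein beta subunit, and Anxa9, an annexin, had log2 fold changes of 2.11 and 1.52 at low levels of 2.66 and 4.66 CPM in Piezo Gel+US. Zp2, an egg coat glycoprotein, measured 0.0853 ± 0.103 CPM in Gel+US and 1.94 ± 0.951 in Piezo Gel+US (log2 fold change 4.39, 95% interval 2.07 to 6.72).

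By the edgeR quasi-likelihood test 0 of 17066 genes were called, and the smallest adjusted p, which all 10 genes above share, was 0.994. At an unadjusted p below 0.05 there were 359 genes, 236 higher and 123 lower, against 853 expected by chance. DESeq2 called 0 genes, with 652 of its 23195 at that level. With the replicate number as a block 0 genes were called and 986 were at that level, above the 853 of chance. Limma-voom with quality weights also called 0, with 2413 of the 17066 genes at that level. Its weight was 7.74 for Gel+US replicate 1 and at most 2.41 for any other library. With 1 library left out the number at that level ran from 141 to 775. Values of the groups did not overlap for 1162 genes, or 6.81% of those tested, where chance gives 10% if the replicate numbers are ignored. The libraries of a group resembled each other no more than those of different groups: the correlation of log2 CPM across genes averaged 0.940 within groups and 0.946 between groups. The mean between groups includes the pairs of equal number (0.979, 0.937 and 0.955 for replicates 1 to 3). Of 53 gene lists tested, camera with the preset correlation called 15, 3 higher and 12 lower, while an estimated correlation called 0 (2 at an unadjusted p below 0.05) and fry called 0 (1 at that level). Among the 10 ways of splitting the libraries into 3 and 3, 8 called at least 15 lists and the highest other split called 35.

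**Figure D1:**
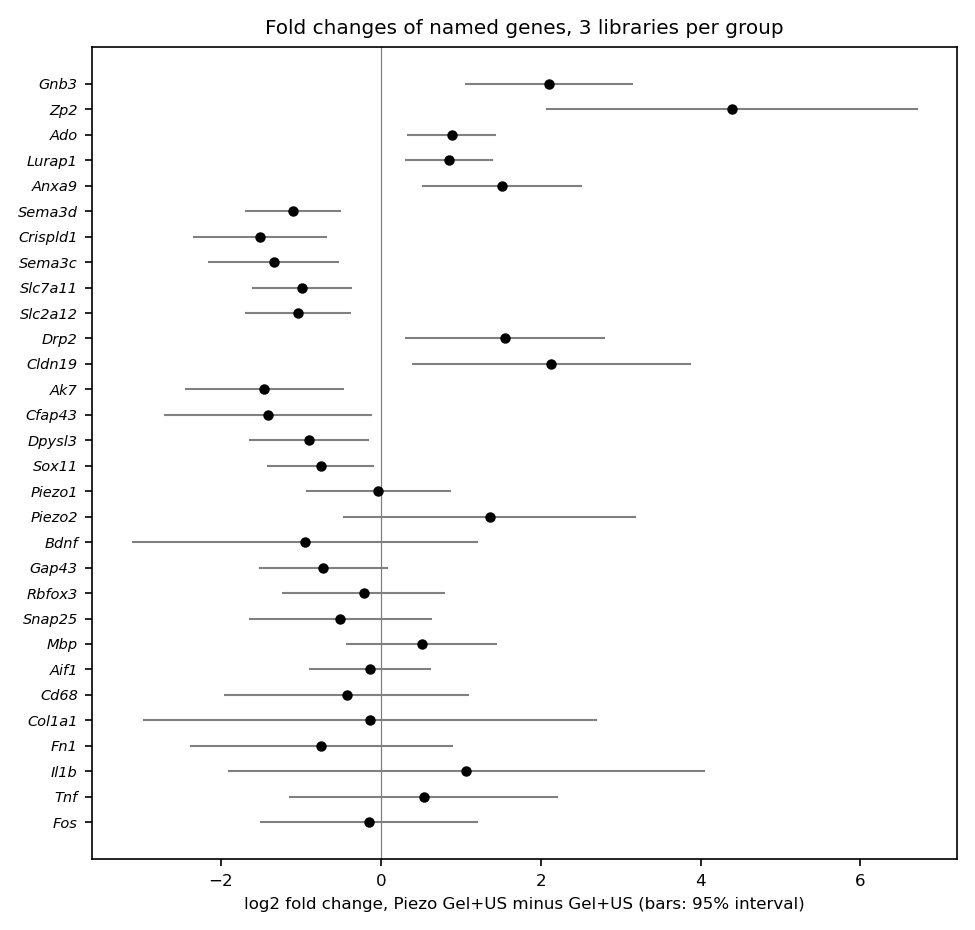
Log2 fold changes of named genes, Piezo Gel+US minus Gel+US, with 95% intervals from the edgeR fit (3 libraries per group). Points are genes of lowest p in each direction, members of called lists and genes fixed in advance, and all of them had an adjusted p of at least 0.994.

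Schwann cell genes, the myelin programme of peripheral nerve, were higher as a group in Piezo Gel+US. Of 16 members tested, 14 were higher, with a median log2 fold change of 1.54. Cldn19, a tight junction protein of Schwann cells, measured 64.7 ± 12.7 CPM in Gel+US and 284 ± 291 in Piezo Gel+US (log2 fold change 2.14, 95% interval 0.39 to 3.88), and Drp2, part of the periaxin complex on the outside of peripheral myelin, measured 294 ± 73.8 CPM in Gel+US and 864 ± 544 in Piezo Gel+US (log2 fold change 1.56, 95% interval 0.31 to 2.81). The list was called by camera at the preset correlation (adjusted p = 9.23e-10), with adjusted p = 0.930 with an estimated correlation, and 0 members passed adjusted over the list alone. Without Piezo Gel+US replicate 2 the median was 0.52, with a camera adjusted p of 1.75e-07, and the log2 fold changes of Cldn19 and Drp2 were 0.85 and 0.99. The list scores averaged 0.48 ± 0.92 in Piezo Gel+US and -0.48 ± 0.34 in Gel+US (exact two-sided permutation p = 0.2, n = 3 each), a test that ignores the replicate numbers. In each of the 3 pairs of equal number the score was higher in Piezo Gel+US than in Gel+US (-0.18 and -0.74, 1.53 and -0.10, 0.11 and -0.61 for replicates 1 to 3). These pair differences were not tested.

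**Figure D2:**
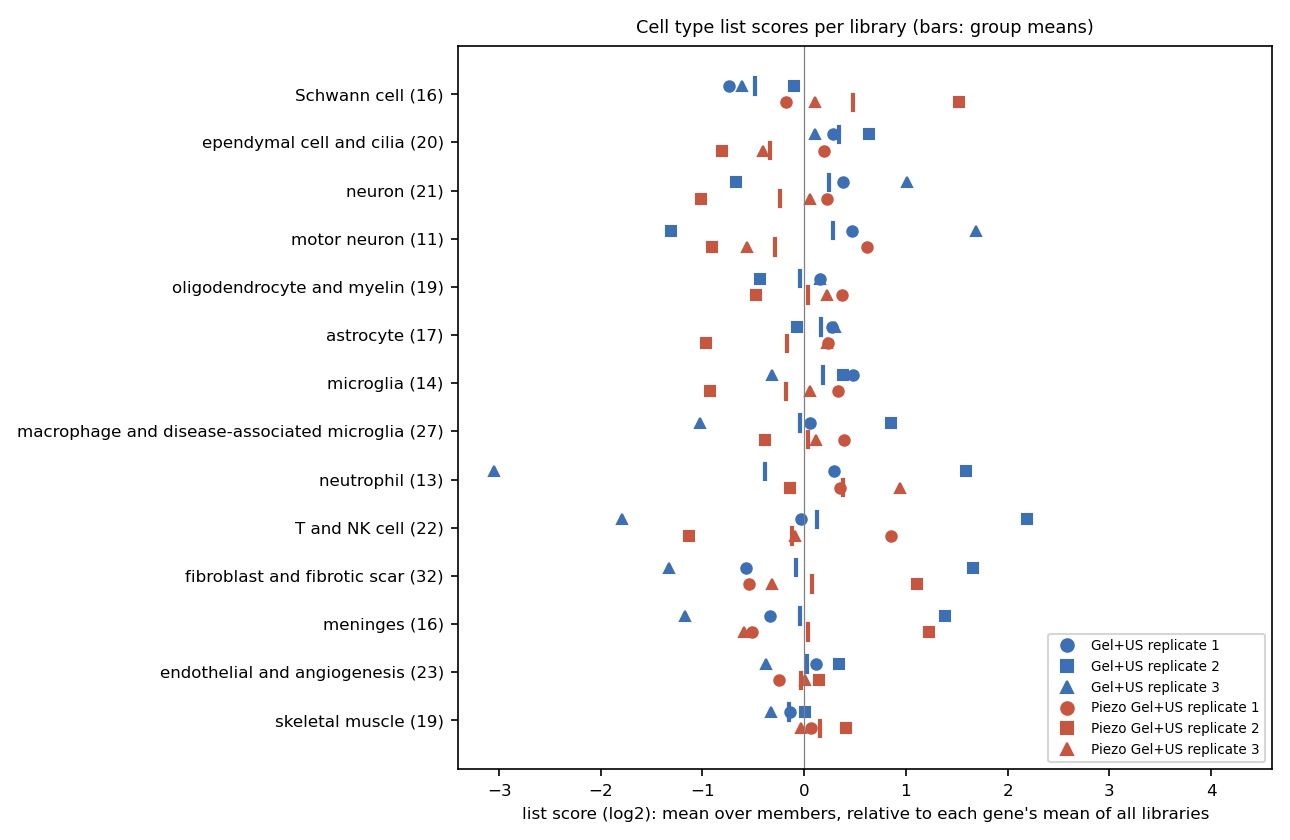
Scores of 14 cell type lists in each of the 6 libraries, on a log2 scale relative to each gene's mean, with the members tested in brackets. Symbols mark the replicate, colours the group and vertical bars the group means. The Schwann cell score of Piezo Gel+US replicate 2 was 1.53, and the neutrophil score of Gel+US replicate 3 was -3.05.

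Genes of ependymal cells and motile cilia were lower as a group, as were genes of axon guidance. In the ependymal list 18 of 20 members were lower (median -0.47), among them Ak7, an adenylate kinase of motile cilia (log2 fold change -1.46, 95% interval -2.45 to -0.46), and Cfap43, a flagellar axoneme protein (log2 fold change -1.41, 95% interval -2.71 to -0.11). In the axon guidance and growth inhibition list, which holds Sema3c and Sema3d, 29 of 36 members were lower (median -0.37). In the axon growth list 17 of 24 were lower (median -0.17), including Dpysl3, a growth cone protein (log2 fold change -0.90, 95% interval -1.64 to -0.15), and Sox11, a transcription factor of neuronal outgrowth (log2 fold change -0.75, 95% interval -1.42 to -0.081). Gap43, the growth cone marker, measured 83.5 ± 22.6 CPM in Gel+US and 50.8 ± 17.8 in Piezo Gel+US (log2 fold change -0.72, 95% interval -1.52 to 0.087). Camera gave adjusted p = 4.63e-06, 1.62e-05 and 0.0433 for the ependymal, guidance and growth lists, and 0 members of any of them passed adjusted over the list alone. With an estimated correlation the adjusted p was 0.930, 0.577 and 0.930. The ependymal and guidance lists were called in all 6 fits that left out a library, whereas the growth list was lost without Gel+US replicate 1, Gel+US replicate 3, Piezo Gel+US replicate 2 or Piezo Gel+US replicate 3 (adjusted p up to 0.302). The ependymal, guidance and growth calls were each lost with the Schwann cell score as covariate, a choice made after seeing the data. The ependymal median lay between -0.97 without Piezo Gel+US replicate 1 and -0.34 without Gel+US replicate 2, and the guidance median between -0.57 without Piezo Gel+US replicate 1 and -0.26 without Piezo Gel+US replicate 2. Cfap43 had a log2 fold change of -0.94 without Gel+US replicate 2 and Gap43 of -0.46 without Piezo Gel+US replicate 2.

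Neuronal genes lay lower in Piezo Gel+US, and the score of the neuron list was lowest in Piezo Gel+US replicate 2 (-1.01) and highest in Gel+US replicate 3 (1.01). In each of the 3 pairs of equal replicate number it was lower in Piezo Gel+US than in Gel+US (0.23 and 0.39, -1.01 and -0.67, 0.061 and 1.01), differences that were not tested. The fibroblast score ran the other way, 1.11 and -1.33 in Piezo Gel+US replicate 2 and Gel+US replicate 3, with r = -0.943 over all 6 (exact permutation p = 0.00972, a relation tested after the values were seen). All 21 tested members of the neuron list were lower (median -0.45), with log2 fold changes of -0.78 for Syt1, the calcium sensor of synaptic vesicles, -0.96 for Stmn2 and -0.50 for Snap25. Inhibitory synapse genes had 20 of 20 members lower (median -0.59), including the GABA receptor subunit Gabrb2 (-0.88). Glutamatergic synapse genes had 20 of 21 lower (median -0.45), including the vesicular transporter Slc17a6 (-0.58). Voltage-gated calcium channels had 15 of 17 lower (median -0.37, Cacna1g -0.69 and Cacna2d1 -0.97), and sodium and potassium channels 18 of 20 (median -0.25, Kcnc2 -0.65). The sensory ganglion list, with the neuropeptides Sst (-0.84) and Tac1 (-1.07), had 11 of 14 members lower (median -0.84). It shares Isl1 with the motor neuron list and Nefh with the neuron list, so it does not mark ganglion tissue alone. The camera adjusted p was 1.24e-04 for the neuron, 3.56e-06 for the inhibitory, 3.55e-04 for the glutamatergic, 0.00153 for the calcium channel, 0.00887 for the sodium and potassium channel and 0.0433 for the sensory ganglion list. It was 0.930 for each of these lists with an estimated correlation, and 0 members passed adjusted over the list alone. Without Gel+US replicate 3 none of these 6 lists was called (medians from -0.25 for the glutamatergic to 0.014 for the sensory ganglion list; neuron -0.011, adjusted p = 0.782). Without Piezo Gel+US replicate 2 only the inhibitory list was (neuron median -0.23, adjusted p = 0.320), and the glutamatergic, sensory ganglion and both channel lists were also lost without Gel+US replicate 1. A fit with the Schwann cell score as covariate, chosen after seeing the data, called the neuron, glutamatergic and sodium and potassium channel lists higher. The inhibitory, calcium channel and sensory ganglion calls were lost in that fit. Single genes moved as well: without Gel+US replicate 3 the log2 fold changes of Stmn2, Snap25 and Gabrb2 were -0.011, -0.011 and -0.27, and without Gel+US replicate 1 those of Cacna2d1, Sst and Tac1 were -0.60, -0.48 and -0.24. Without Piezo Gel+US replicate 2 Cacna1g and Kcnc2 had -0.40 and -0.42. Slc17a6 had -0.87 without Gel+US replicate 2, and ranged from -0.89 to -0.40 over the fits that left out 1 library.

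Astrocyte and microglia genes also lay lower in Piezo Gel+US. In the astrocyte list 16 of 17 members were lower (median -0.17), including the water channel Aqp4 (-0.58) and the glutamate transporter Slc1a3 (-0.63). In the microglia list 13 of 14 were lower (median -0.31), including the purinergic receptor P2ry12 (-0.50) and Olfml3 (-0.87). Both were called by camera (adjusted p = 0.0299 and 0.0433), with adjusted p = 0.930 with an estimated correlation, and 0 members passed adjusted over the list alone. Piezo Gel+US replicate 2 had the lowest score of each list (-0.96 and -0.93), and without it the medians were 0.073 and 0.058 (adjusted p = 0.416 and 0.768). Without it the log2 fold changes of Aqp4, Slc1a3 and P2ry12 were -0.30, -0.32 and -0.21, and that of Olfml3 was 0.60 without Gel+US replicate 2. The astrocyte call was also lost without Gel+US replicate 1 or 3 (adjusted p = 0.114 and 0.233), and the microglia call without Gel+US replicate 1 or 2 (adjusted p = 0.450 and 0.283). With the Schwann cell score as covariate the astrocyte list was called higher and the microglia call was lost.

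Cell cycle genes lay lower, and cholesterol synthesis and ribosomal protein genes higher. In the cell cycle list 29 of 30 members were lower (median -0.47), including the checkpoint kinase Bub1 (-0.61) and the mitotic cyclin Ccnb2, which measured 3.09 ± 1.00 CPM in Gel+US and 1.54 ± 0.739 in Piezo Gel+US. In the cholesterol synthesis and efflux list 20 of 21 were higher (median 0.34), including the sterol enzymes Lss (0.34) and Msmo1 (0.77). Of the 21 members 15 were highest in Piezo Gel+US replicate 2, where 12 of 16 Schwann cell genes were also highest. All 39 ribosomal protein genes were higher (median 0.26, Rpl22 0.34 and Rpl32 0.48). Camera gave adjusted p = 2.58e-04, 2.58e-04 and 1.14e-06 in that order, and 0.930 for each with an estimated correlation, with 0 members past the test adjusted over the list alone. The cell cycle call was lost without Gel+US replicate 2 or Piezo Gel+US replicate 3 (medians -0.0024 and -0.22, adjusted p = 0.591 and 0.246), and the cholesterol call without Gel+US replicate 2 or Piezo Gel+US replicate 2 (medians 0.17 and 0.020, adjusted p = 0.255 and 0.154). The ribosomal call was lost without Gel+US replicate 3 (median 0.055, adjusted p = 0.112). With the Schwann cell score as covariate, a choice made after seeing the data, the cholesterol and ribosomal calls were lost. Bub1 had a log2 fold change of -0.31 without Gel+US replicate 2, Msmo1 of 0.14 without Piezo Gel+US replicate 2 and Rpl32 of 0.20 without Gel+US replicate 3.

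The mechanosensitive channel Piezo1 had the same mean level in both groups within its spread, 61.5 ± 32.5 CPM in Gel+US and 60.3 ± 6.18 in Piezo Gel+US (log2 fold change -0.029, 95% interval -0.94 to 0.88). Piezo2, its relative in touch-sensing neurons, measured 14.0 ± 6.28 CPM in Gel+US and 36.0 ± 38.1 in Piezo Gel+US (log2 fold change 1.36, 95% interval -0.47 to 3.20), with 79.9 CPM in Piezo Gel+US replicate 2, and without that library its log2 fold change was -0.0035. The neurotrophin Bdnf measured 2.61 ± 2.08 CPM in Gel+US and 1.35 ± 1.19 in Piezo Gel+US (log2 fold change -0.95, 95% interval -3.12 to 1.22). Mbp, a major myelin protein of the cord and of nerve, measured 20818 ± 4873 CPM in Gel+US and 29663 ± 6950 in Piezo Gel+US (log2 fold change 0.51, 95% interval -0.44 to 1.46). The neuronal nuclear protein Rbfox3 had a log2 fold change of -0.21 and the macrophage genes Aif1 and Cd68 of -0.13 and -0.43. Col1a1, the main scar collagen, ranged from 183 CPM in Gel+US replicate 3 to 2194 in Gel+US replicate 2 (log2 fold change -0.14, 95% interval -2.98 to 2.70), and fibronectin, Fn1, had a log2 fold change of -0.75. The cytokines Il1b and Tnf had log2 fold changes of 1.07 and 0.54 with intervals of -1.91 to 4.05 and -1.14 to 2.22, Il6 had 0 to 6 counts per library, and the activity gene Fos had a log2 fold change of -0.15. Leaving out 1 library moved most of these values: without Gel+US replicate 2 the log2 fold changes of Piezo1, Cd68, Col1a1, Fn1 and Fos were 0.44, 0.37, 2.01, 0.28 and 0.64, and without Piezo Gel+US replicate 2 those of Rbfox3 and Aif1 were 0.072 and 0.054. Bdnf had -0.19 without Gel+US replicate 1, and Il1b and Tnf had 0.48 and 0.049 without Gel+US replicate 3. The adjusted p of each gene in this group that was tested was at least 0.994.

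Scar, T cell and neutrophil lists were not called between the groups. The fibroblast and fibrotic scar list had 12 members higher and 20 lower (median -0.23, adjusted p = 0.587), the T and NK cell list 21 of 22 lower (median -0.73, adjusted p = 0.0764) and the neutrophil list 8 of 13 higher (median 0.17, adjusted p = 0.117). For the fibroblast list the camera direction was up while the median was below 0. Oligodendrocyte and myelin genes had 11 of 19 higher (median 0.10, adjusted p = 0.0743), and mechanosensitive channels 13 of 20 lower (median -0.058, adjusted p = 0.734). With the replicate number as a block, 3 further lists were called as higher: fibroblast and fibrotic scar (median 0.20, adjusted p = 8.05e-04), immediate early genes (0.0319, against 0.332 without the block) and the TNF and NF-kB pathway (0.00995, against 0.0627). These calls used the preset correlation, and without the block the adjusted p of the lists was 0.990, 0.990 and 0.930 with an estimated correlation. The fibroblast list was called higher without Gel+US replicate 2 (median 1.33) and without Piezo Gel+US replicate 1 (0.036), and lower without Gel+US replicate 3 (-0.66) or Piezo Gel+US replicate 2 (-0.97). The T and NK cell list was called lower without Gel+US replicate 1 (-1.08), Gel+US replicate 3 (-1.30) or Piezo Gel+US replicate 1 (-1.68) and higher without Gel+US replicate 2 (0.83). The neutrophil list was called higher without Gel+US replicate 1 (0.086), Gel+US replicate 2 (adjusted p = 4.64e-05) or Piezo Gel+US replicate 2 (0.43) and lower without Gel+US replicate 3 (-0.33). The oligodendrocyte list was called higher without Gel+US replicate 1 (0.26), Gel+US replicate 3 (0.11) or Piezo Gel+US replicate 2 (0.36) and with library size alone as scaling, while its median was -0.18 without Piezo Gel+US replicate 1 and -0.080 with the block. The calls with a library left out used the preset correlation. With all libraries and an estimated correlation the camera adjusted p was 0.990 for T and NK cell, 0.990 for neutrophil and 0.930 for oligodendrocyte genes.

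Libraries also differed in the Hox genes that mark position along the body axis. Hoxd11 measured 13.5 CPM in Gel+US replicate 3 and 6.89 in Piezo Gel+US replicate 2, and at most 0.0517 in the other 4 libraries. Hoxc11 measured 11.8 and 13.5 CPM in the same libraries and at most 0.301 elsewhere, and Hoxa11 9.02 and 7.24 there, 4.04 in Piezo Gel+US replicate 3 and at most 0.427 in the others. Hoxd10 measured at least 15.6 CPM in Gel+US replicate 3, Piezo Gel+US replicate 2 and Piezo Gel+US replicate 3 and at most 5.55 in the others, while Hoxc10 lay between 23.9 and 38.4 CPM in all 6 libraries. With both Hox11-rich libraries left out, a choice made after seeing the data, the Schwann cell, ependymal, guidance, cell cycle and cholesterol lists were still called in their direction, and the neuron list was called higher (median 0.27, adjusted p = 0.00561). These calls rest on 2 libraries per group and the preset correlation, and with all 6 libraries the neuron list had adjusted p = 0.930 with an estimated correlation.

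**Figure D3:**
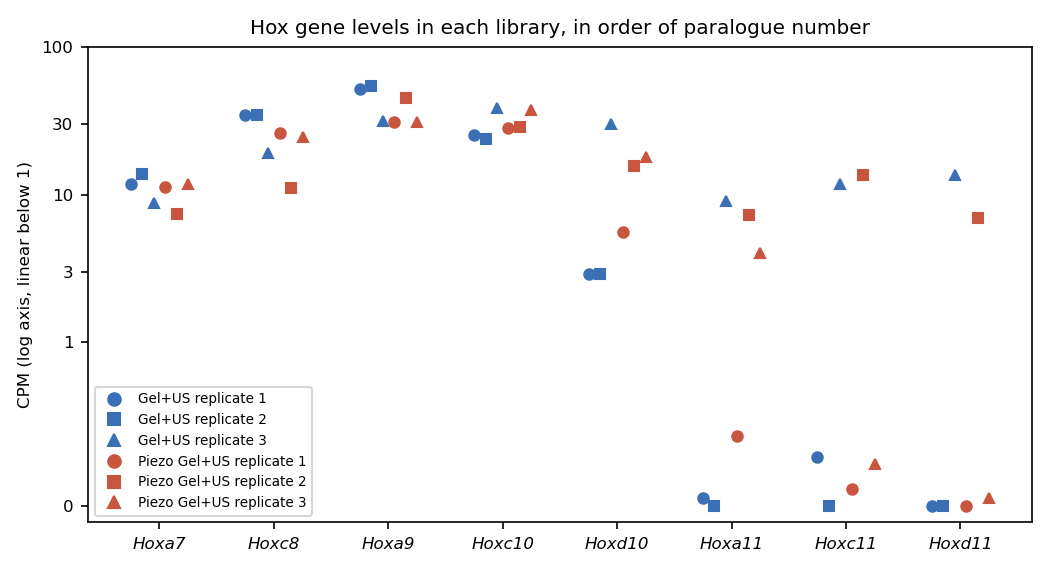
CPM of 8 Hox genes in each library, in order of paralogue number, on a logarithmic axis that is linear below 1. Hoxd11 reached 13.5 CPM in Gel+US replicate 3 and 6.89 in Piezo Gel+US replicate 2, 1 library of each group, while Hoxc10 was similar in all 6.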

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

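The omission of both Hox11-rich libraries, the scar score and Schwann score covariates, and the matching of list members by symbol were chosen after seeing the data. The count of 0 called genes held under every scaling, filter, test, threshold, block, covariate and left-out library that was run, with 141 to 2413 genes at an unadjusted p below 0.05. The highest number was that of limma-voom quality weights, where chance gives 853. That fit weighted Gel+US replicate 1 at 7.74 against 0.419 and 0.438 for Gel+US replicates 2 and 3, and Piezo Gel+US replicate 2 at 0.210. Its Gel+US level thus rested mostly on 1 library. For lists, 15 were called, 0 with an estimated correlation and 0 by fry, 12 to 28 with a library left out (28 without Gel+US replicate 2, 22 without Gel+US replicate 3) and 25 without both Hox11-rich libraries, of which 5 were shared with the 15. Library size alone as scaling called 12 (axon growth, astrocyte, microglia and dorsal root ganglion lost, oligodendrocyte gained), the stricter filter and protein-coding genes 12 each (axon growth, microglia and dorsal root ganglion lost), and no filter 17 (axon growth lost, T and NK cell gained as lower, skeletal muscle and the TNF and NF-kB pathway as higher). Voom quality weights called 15, of which 11 were shared (cholesterol, astrocyte, axon growth and dorsal root ganglion lost). Gained there were endothelial and interferon response as lower and the TNF and NF-kB pathway and oxidative phosphorylation as higher. The scar covariate called 14 (axon growth and dorsal root ganglion lost, the TNF and NF-kB pathway gained as higher). Matching by symbol called 15 (microglia lost, motor neuron gained as lower). With the Schwann score as covariate 15 were called and 1, cell cycle, was shared, where the loss of the Schwann cell list was fixed by construction. The ependymal and guidance lists were also lost. The neuron, glutamatergic synapse, sodium and potassium channel and astrocyte lists were called higher instead of lower. The replicate block called 0 genes, with 986 at an unadjusted p below 0.05, and 18 lists, and apart from the 3 lists gained it changed no other call. Only 3 of the 15 calls held in every fit without 1 library. Of 881 comparisons of single genes named in the text 843 kept their direction and 38 reversed, and of 954 list medians 899 stayed within the spread, 36 moved and 19 reversed. The spread was the pooled SD within groups of the list score over all 6 libraries. A list that varied widely between libraries, such as neutrophil (SD 2.39 in Gel+US), could therefore move far and still count as within it. For medians, a reversal was counted only in the 15 called lists. Other lists also changed sign, such as T and NK cell (-1.68 to 0.83 with 1 library left out) and fibroblast (-0.97 to 1.33), and were counted as within the spread or moved. The causes of these reversals were not tested.

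With the Schwann score as covariate, list medians were -0.00043 for Schwann cell (near 0 by construction, as the covariate is this list's own score, and counted among the reversals), -0.082 ribosomal protein, 0.13 inhibitory synapse, 0.28 neuron, 0.22 glutamatergic synapse, 0.29 calcium channels, 0.28 sodium and potassium channels, 0.40 astrocyte, 0.22 dorsal root ganglion neuron and 0.30 microglia. In the same fit log2 fold changes were 0.026 for Stmn2, -0.033 Msmo1, 0.13 Slc1a3, 0.082 Aqp4, 0.22 P2ry12, -0.67 Piezo2, 0.66 Bdnf, 0.59 Rbfox3, 0.22 Snap25 and 0.16 Aif1. Without both Hox11-rich libraries, medians were -0.085 for ribosomal protein, 0.093 inhibitory synapse, 0.27 neuron, 0.031 calcium channels, 0.22 sodium and potassium channels and 0.14 astrocyte, and fold changes 0.076 for Gabrb2, 0.30 Stmn2, -0.079 Piezo2, 0.27 Rbfox3, 0.26 Snap25 and -0.090 Tnf. The scar score covariate gave 0.063 for Piezo1 and 0.026 for Col1a1, the replicate block 0.11 and 0.26, and voom quality weights 0.082 and 0.41, with 0.23 for Cd68 and 0.17 for Fos. Leaving out 1 library gave ranges of -0.35 to 0.44 for Piezo1, -0.0035 to 1.76 Piezo2, -0.52 to 0.072 Rbfox3, -0.38 to 0.054 Aif1, -0.82 to 0.37 Cd68, -1.65 to 2.01 Col1a1, -1.22 to 0.28 Fn1, -0.51 to 0.64 Fos and -1.37 to 0.60 Olfml3, and median ranges of -0.48 to 0.073 for astrocyte, -1.15 to 0.014 dorsal root ganglion neuron and -0.70 to 0.058 microglia.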

Other observations

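The tests on muscle genes, Hox genes and the relation of neuronal to scar genes were chosen after the values per library had been seen, as were the scar score covariate and the omission of libraries by their Hox11 level. Libraries of the same group also differed in their cell content. Motor neuron genes had a score of 1.69 in Gel+US replicate 3 and -1.31 in Gel+US replicate 2: Chat, the acetylcholine-synthesising enzyme, measured 99.8 and 3.55 CPM there, and the vesicular transporter Slc18a3 255 and 5.50. Neurofilament Nefm measured 5398 CPM in Gel+US replicate 3 and 459 in Gel+US replicate 2. Gel+US replicate 2 had the highest T and NK cell score (2.19), with 368.6 CPM of Cilp and 422.6 of Comp, matrix proteins of cartilage and tendon, against 0.952 and 4.51 in Gel+US replicate 3. Granulocyte genes were near the floor in Gel+US replicate 3, where S100a9 measured 1.05 CPM, against 40.8 to 125 in the other 5 libraries. Haemoglobin transcripts took 4.99% of counts in Gel+US replicate 2 and 0.127% in Gel+US replicate 3. These genes were picked after their values were seen.

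Neuronal and scar genes moved against each other across the 6 libraries, the neuron and fibroblast scores having Pearson r = -0.943 (exact permutation p = 0.00972, adjusted p = 0.0292 over 6 relations) and Spearman rho = -0.943 (exact permutation p = 0.0167, adjusted p = 0.05, which is not below the threshold), and r was -0.981 without the 2 libraries farthest from the median neuron score. The neuron score also ran against the Schwann cell score, with r = -0.809 (exact permutation p = 0.0361, adjusted p = 0.0722) and r = -0.504 without the same 2 libraries. A candidate explanation is that the pieces held different proportions of scar and spared cord, a hypothesis found on these data that oligodendrocyte genes, also of the cord, did not clearly share: against the fibroblast score they had r = -0.884 (exact permutation p = 0.0542), 0.427 without the 2 libraries farthest from their median, and rho = -0.486 (exact permutation p = 0.356). With the fibroblast score as covariate 0 genes were called, with 857 at an unadjusted p below 0.05 against 359 without the covariate and 853 expected by chance. Because the fit has 3 residual degrees of freedom and the simulation recovered 2 of 50 genes changed 2-fold even without a covariate, the 0 calls leave open whether unequal scar content hid group differences.

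Schwann cell genes stood highest in Piezo Gel+US replicate 2, with a score of 1.53 against -0.74 to 0.11 in the other 5 libraries. Nerve root or other tissue taken with the piece may contribute. In that library the skeletal muscle genes Acta1, Atp2a1, Ckm and Tnni2 measured 72.1, 13.5, 10.0 and 5.18 CPM, against at most 3.00, 1.44, 0.333 and 0.301 elsewhere, which goes with such tissue. Ckm and Tnni2 were below the count filter. Without the filter camera called the muscle list higher at the preset correlation (adjusted p = 0.0314). With the filter it did not (adjusted p = 0.313, and 0.930 with an estimated correlation). Both are comparisons of the groups, not tests of this library. Of 19 tested members of the muscle list, 6 (31.6%, exact binomial 95% interval 12.6% to 56.6%) were highest there and 5 lowest, where chance gives 1 in 6. A response shared by the Piezo Gel+US libraries also stays open, as the median log2 fold change of the list without that library was 0.52, above 0 but under the bound written down beforehand. The tissue source and the treatment cannot be told apart for this library.

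Hox11 transcripts, which mark caudal levels, were abundant in Gel+US replicate 3 and Piezo Gel+US replicate 2. Of the 3 Hox11 genes, 0 had all Piezo Gel+US libraries above all Gel+US libraries, which follows from how the pattern was found and is no separate test of the treatment. Connective tissue or muscle taken along is argued against in Gel+US replicate 3, whose fibroblast score of -1.33 was the lowest. In Piezo Gel+US replicate 2 the fibroblast score of 1.11 and a skeletal muscle score of 0.41, both above the median of the other libraries, go with it. However, Gel+US replicate 2 had the highest fibroblast score (1.66), a skeletal muscle score of 0.012 and 0 counts of Hoxa11, Hoxc11 and Hoxd11. A high fibroblast score alone therefore did not go with Hox11 transcripts, and that list also holds scar genes of the lesion. Pieces from different levels of the cord may also account for the Hox11 transcripts. Only 2 of 9 Hox5 to Hox8 genes (22.2%, exact binomial 95% interval 2.81% to 60.0%) had their 2 lowest levels in Gel+US replicate 3 and Piezo Gel+US replicate 2. Chance gives 1 in 15, so the share decides neither way. The test asks for both libraries at once and cannot detect a different level of 1 piece alone. In Gel+US replicate 3, Hoxa5, Hoxc5 and Hoxc6 had their lowest levels (35.5, 4.51 and 13.7 CPM). Hoxd8 had its highest level there (78.3 CPM), and the rest of these genes lay between their extremes. In Piezo Gel+US replicate 2, Hoxa6, Hoxa7, Hoxb8 and Hoxc8 had their lowest levels (10.5, 7.34, 29.6 and 11.02 CPM). Hoxc5 had its highest level there (14.8 CPM), and the others of these genes lay between their extremes. How often 1 library alone holds the lowest level was not tested, so different levels of the pieces stay open.

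Among the 10 ways of splitting the 6 libraries into 3 and 3, all 10 called 0 genes, the highest of the other splits included. The real split called 15 lists and the highest other split 35, and 8 splits called at least as many. With 10 splits the share cannot fall below 0.1, so the number of splits is too small for a share under 0.05. Of the 4 splits that part all 3 number pairs, the real one called 15 lists and the others 27, 25 and 11, while splits that keep some numbers together called 7 to 35. The split with Gel+US replicates 1 and 3 and Piezo Gel+US replicate 1 against the rest had 2156 genes at an unadjusted p below 0.05, against 359 in the real split, which points to a structure of the samples other than the groups.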
